A study of Mus musculus with 6 samples.

How the data were processed

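The deposited values are intensities, 1 per probe set and array, for 45101 probe sets of the Affymetrix Mouse Genome 430 2.0 array. Per the labels' protocols, heparin was injected before death, the right lung was flushed with saline, RNA was purified on silica columns and the biotin label followed the manufacturer's manual. The algorithm that turned probe brightness into these deposited intensities is not given in the sources used here. On every array the mean intensity after trimming 2% at each end was 500.0, so the deposited intensities carry a common scaling. Intensities are on a linear scale with no value below 0. Each array came from an individual mouse, per the labels, with 2 mice in each of 3 groups. The labels name no batch and nothing that pairs mice across groups. The label of control 1 does not state the sex of that mouse, while the description of the whole series states that all were female.

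Values were turned into log2(intensity + 16), so differences of dim probe sets are understated. Array medians on that scale spanned 0.127, under the limit of 0.2 set beforehand, and no further normalization was applied. The 64 control probe sets were left out, and so were the 18015 probe sets in the lower 40% by mean over all 6 arrays (below an intensity of about 74.9), which left 27022. The platform annotation gave 1 gene symbol for 34958 probe sets and several for 932, and it did not list 9211, which are unnamed here. By gene identifier, 34754 of the single-symbol probe sets matched a RefSeq gene table of mouse assembly GRCm38.p6, and 0 symbols changed. No coordinates are given because the probe table names no genome build.

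With R 4.3.3 and limma 3.58.1, 1 mean per group was fitted to all 6 arrays (3 residual degrees of freedom, 5.06 prior degrees of freedom), and 4 contrasts were tested with moderated statistics that follow the intensity trend. All tests were two-sided, with Benjamini-Hochberg adjustment at 0.05 over the probe sets. An exact permutation test of 2 against 2 arrays cannot go below p = 0.333, and of 4 against 2 not below p = 0.0667, so none was used for calls.

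Before the data were examined, 48 gene lists were fixed: 26 pathways, 21 cell types and 1 of sex-linked control genes. Of these, 45 had at least 4 measured members among 12557 genes, each represented by the probe set with the highest mean. The thyroid and parathyroid list had 1 measured member and the squamous and esophageal epithelium list 2, so they were not tested. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 45 lists within a comparison. The same test with an estimated correlation and limma's fry were run beside it. With the preset correlation 6, 7, 9 and 6 lists passed for R899X normal RVSP against control, R899X high RVSP against control, R899X high against normal RVSP and all R899X against control; with an estimated correlation 0 passed in each, and with fry 0 passed in each, for one direction or mixed. The mean, median and test of a list differed in sign for 4, 10, 10 and 8 lists. Besides Mb and Ckm of the skeletal muscle list, no member of a tested list passed when adjusted over the list alone. That adjustment was made within each of the 45 lists and not across lists or comparisons, so some members would pass by chance.

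Named genes were chosen by a rule fixed at the same time as the lists. In each direction it took up to 12 genes of largest difference that passed, filled up with those of unadjusted p under 0.01, when the arrays of the 2 sides did not overlap. Only probe sets with 1 gene symbol that is not a clone or model name counted, and other probe sets of a gene were checked for direction. Bmpr2, Tagln and the sex-linked genes were always named, as were up to 4 members of a described list. Intensities of a gene are given in the order of replicates 1 and 2, which follow accession order only.

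The procedure was tested on simulated data with 200 of 27022 probe sets changed between R899X high RVSP and control, in 10 simulations. With spreads drawn from the fitted prior, 14% of 2-fold, 79.4% of 4-fold, 96% of 8-fold and 99.4% of 16-fold changes were recovered, and 5.87% of calls were false. With the fitted spreads used as the true ones, 38.8% of 2-fold and 96.6% of 4-fold changes were recovered, and 9.56% of calls were false, above the nominal 5%. In simulated lists of 15 genes for the same comparison (12557 genes), 25% of 100 unchanged lists passed the preset-correlation test when their genes were correlated at 0.4, and 0% passed with the estimated correlation. Of lists shifted by 0.5 with that correlation between genes, 99% and 0% passed. Of shifted lists of independent genes, 100% and 99% passed. In the data, estimated correlations of lists that passed ranged from 0.00521 for adipocyte to 0.775 for cardiac muscle markers. Those of immediate early genes (0.635), ciliated cell markers (0.631) and B cell and plasma cell markers (0.491) also exceeded 0.4. For lists correlated above 0.4, the share of false calls was not simulated.

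Alternatives covered the filter on dim probe sets, normalization, pseudocount, variance model, array weights, the arrays in the fit, the threshold, the choice of probe set per gene, the list test and leaving out each array. Added after seeing the data were a fit without control 1 and R899X normal RVSP 1 together and a fit with the beta-actin 3'/5' ratio as a covariate.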

Results

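Gene expression was measured in whole lung homogenate of 6 female FVB/N mice, 1 Affymetrix Mouse Genome 430 2.0 array per mouse. The mice fell into 3 groups of 2. Control mice carried only SM22-rtTA, a doxycycline-activated transactivator driven by the promoter of Tagln (SM22), a smooth muscle gene. The other mice also carried a doxycycline-responsive BMPR2-R899X transgene. BMPR2 is a receptor for bone morphogenetic proteins, and R899X is a truncating mutation of it. Of these mice, 2 had right ventricular systolic pressure (RVSP) close to normal at death and 2 had high RVSP. All received doxycycline from 4 weeks of age for 9 weeks and were killed at 13 weeks. The comparisons address the effect of the mutation in lung with and without raised RVSP. Median intensity per array ranged from 128 to 141. Each group mean rests on n = 2 mice, and that number limits the precision of every value. Values after ± are standard errors of log2 differences from limma unless stated otherwise.

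Bmpr2 was read by 3 probe sets with 1 gene symbol. The brightest had an intensity between 15398 and 19768 on all arrays, with a log2 difference of 0.01 ± 0.17 for R899X normal RVSP against control and -0.13 ± 0.17 for R899X high RVSP against control. The dimmest lay between 302 and 460. The intermediate probe set gave 436 and 2047 in the controls, 657 and 1987 in the R899X normal RVSP mice, and 1928 and 2170 in the R899X high RVSP mice. Its difference between R899X high RVSP and control was 1.09 ± 0.69 (adjusted p = 0.876). Whether any of these probe sets detects the transgene transcript was not established, so they do not check the genotype labels. Tagln lay between 4115 and 5622 on the 6 arrays. Xist, transcribed from the inactive X chromosome, was read by 3 probe sets, which lay between 4646 and 7705, between 1589 and 8282, and between 150 and 680, while the probe sets of the Y-linked genes Eif2s3y, Kdm5d and Uty did not exceed 38.8 on any array.

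**Figure D1:**
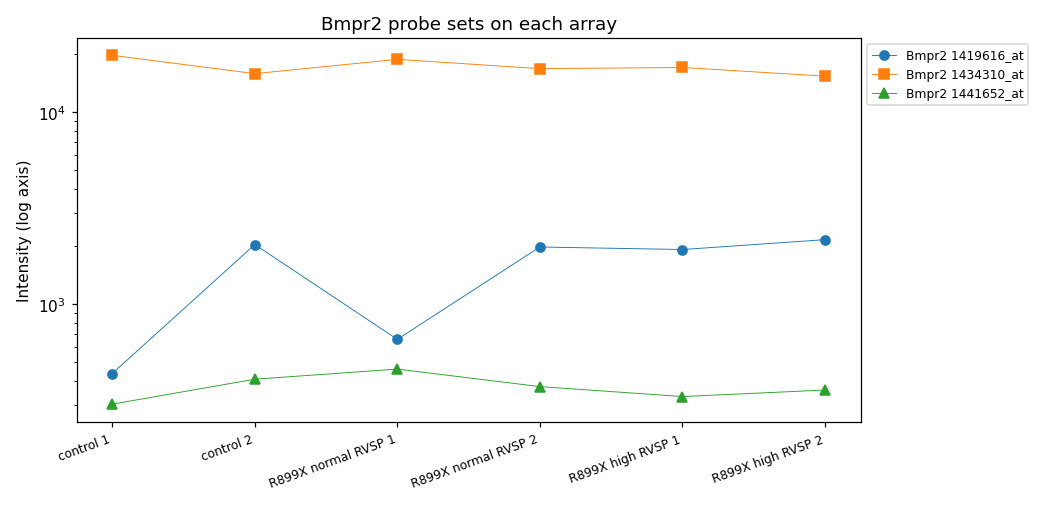
Intensity (log axis) of the 3 Bmpr2 probe sets on each of the 6 arrays, 1 point per array; lines join the points of a probe set and carry no order. The intermediate probe set (circles) read 436 in control 1 and 657 in R899X normal RVSP 1, against 1928 to 2170 in the high RVSP mice, while the brightest stayed between 15398 and 19768.

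Arrays of the same group were no closer to each other than arrays of different groups. The root mean square log2 distance averaged 0.439 over the 3 pairs within a group and 0.437 over the 12 pairs between groups. The first principal component held 35.9% of the variance, and control 1 and R899X normal RVSP 1 had scores of -41.7 and -36.2 on it, against 8.11 to 26.9 for the other arrays. These same arrays had mean distances of 0.496 and 0.492 to the others, against at most 0.420 for the rest. Their 3'/5' intensity ratios for the beta-actin control probe sets were 1.89 and 1.64, above the 1.27 to 1.45 of the other 4 arrays. The corresponding ratios for Gapdh, a glycolytic enzyme, were 0.973 and 0.700, within or below the 0.721 to 1.03 of the others.

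**Figure D2:**
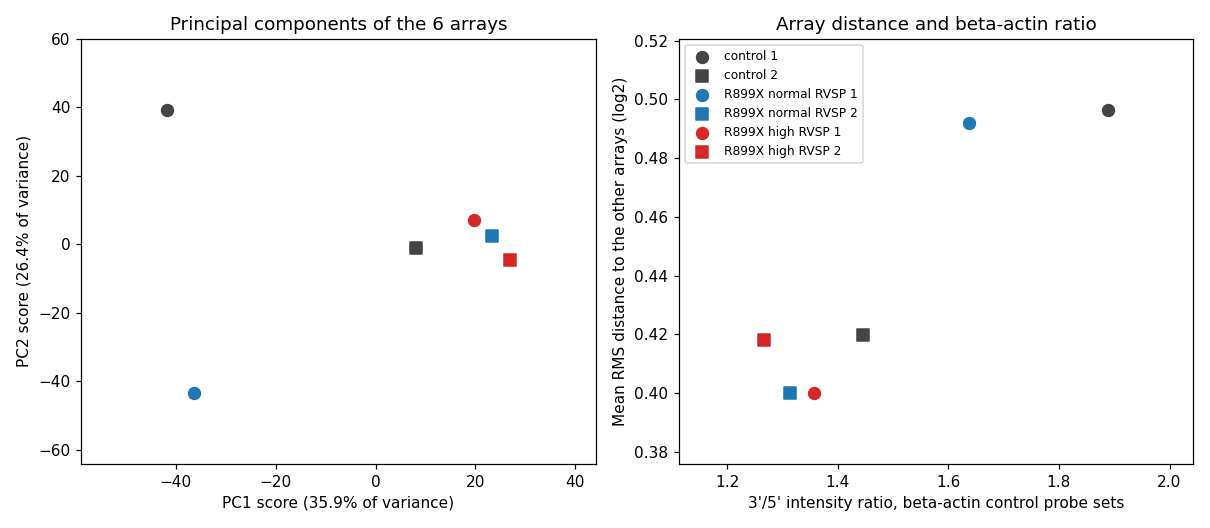
Left, scores of the 6 arrays on the first and second principal components (35.9% and 26.4% of variance); right, the beta-actin 3'/5' intensity ratio (no unit) against the mean root mean square distance to the other arrays (log2). Each point is 1 array; control 1 and R899X normal RVSP 1 lie apart at ratios of 1.89 and 1.64.

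The first comparison, R899X normal RVSP against control, concerns the mutation without raised pressure. Ciliated cell markers were higher as a group, with a mean log2 difference of 0.45 and 14 of 14 measured members higher. Examples are Dynlrb2, a dynein light chain, at 0.68 ± 0.27, and Dnah5, an axonemal dynein heavy chain, at 0.68 ± 0.28. This list had an adjusted p = 3.4e-06 in limma's camera test with a preset correlation, and adjusted p = 0.854 with an estimated correlation. Control 1 alone lay at -0.58 in the mean deviation of these markers, while control 2 lay at 0.08, and without control 1 the difference was 0.12 (adjusted p = 0.421), while without control 2 it was 0.78. Smooth muscle contractile genes were higher by 0.20 on average, with 14 of 17 higher (adjusted p = 0.00619, and adjusted p = 0.854 with an estimated correlation). Among them were Myl9, a myosin light chain, at 0.52 ± 0.17, and Acta2, smooth muscle actin, at 0.34 ± 0.14. Without control 1 or without R899X normal RVSP 1 the mean was 0.11 or 0.13 and the adjusted p was 0.309 or 0.101. Smooth muscle and pericyte markers followed with 10 of 12 higher, a mean of 0.19 and an adjusted p = 0.0387, or adjusted p = 0.941 with an estimated correlation. Without control 1 their mean was -0.02 and without control 2 it was 0.41. The call also ended without R899X normal RVSP 2 (adjusted p = 0.277), R899X high RVSP 1 (adjusted p = 0.0543) or R899X high RVSP 2 (adjusted p = 0.0535). That list shares Acta2 and Cnn1 with the contractile list.

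Skeletal muscle markers had a mean difference of 0.35, with 6 of 7 higher (adjusted p = 0.0215, and adjusted p = 0.854 with an estimated correlation). Mb, myoglobin, which heart muscle also expresses, was 0.73 ± 0.20 higher and was the 1 member past the threshold when adjusted over the list alone (adjusted p = 0.0491); 0 members passed over all probe sets. Without control 2 or R899X normal RVSP 1 the skeletal mean was 0.26 or 0.14 (adjusted p = 0.316 and 0.369), and without R899X normal RVSP 2 it was 0.56. R899X normal RVSP 1 scored 0.45 on this list and 0.49 on the cardiac muscle list, against 0.03 and 0.07 in R899X normal RVSP 2; the cardiac list had a mean of 0.13 with 12 of 18 higher and did not pass (adjusted p = 0.405). Adipocyte markers were higher by 0.44, with 9 of 11 members higher (adjusted p = 0.0236, and adjusted p = 0.854 with an estimated correlation). Adipoq, the hormone adiponectin, had intensities of 46.3 and 303 in the R899X normal RVSP mice and 19.6 and 54.4 in the controls, and Fabp4, a fatty acid carrier, differed by 0.91 ± 0.44. Without R899X normal RVSP 2 the adipocyte mean was 0.04 (adjusted p = 0.706); it was 0.26 without control 1 (adjusted p = 0.278), 0.62 without control 2 (adjusted p = 0.0790) and 0.84 without R899X normal RVSP 1. Genes of the heat shock and unfolded protein response were lower by a mean of -0.23, with 15 of 19 lower (adjusted p = 0.00105, and adjusted p = 0.854 with an estimated correlation). Pdia4, a chaperone of the endoplasmic reticulum, differed by -0.72 ± 0.26, and Hspb1, a small heat shock protein, by -0.50 ± 0.20. Without control 1 the mean of this group was -0.04 (adjusted p = 0.683), without R899X normal RVSP 1 it was -0.15 (adjusted p = 0.142), without both of these arrays it was 0.04, and without control 2 it was -0.42. Target genes of BMP signalling had a mean of 0.10 with 11 of 14 higher and did not pass (adjusted p = 0.405).

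No single probe set passed in this comparison. Of the 24 genes named by rule, Zdhhc12, a palmitoyltransferase family member, had the largest difference at 1.75 ± 0.29, with intensities of 310 and 349 against 68.2 and 109 in the controls. Cyp26b1, which degrades retinoic acid, stood at 1.26 ± 0.27, Nrg1, a ligand of ErbB receptors, at 1.34 ± 0.36, and Ntn5, a netrin, at 1.36 ± 0.36. Rabgap1 and Mrps15, a mitochondrial ribosomal protein, had the most negative differences at -1.54 ± 0.42 and -1.51 ± 0.40, and Clec2d, a C-type lectin, stood at -1.12 ± 0.24. Other probe sets existed for 15 of the 24 genes, and for 8 of these at least 1 pointed the other way. For Ywhaz, 5 of 6 other probe sets did so, and for Rabgap1 and for Mrps15 1 of 2. With limma, 0 of 27022 probe sets passed the Benjamini-Hochberg threshold (smallest adjusted p = 0.987); 1174 had an unadjusted limma p under 0.05 against 1351 expected by chance, and the ordinary linear model also gave 0. Some probe sets passed without control 2, without R899X normal RVSP 2, and without control 1 and R899X normal RVSP 1 together. The last of these fits was chosen after seeing the array distances. Each left a compared group with 1 array and no spread of its own, so their counts are not given.

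The comparison of R899X high RVSP with control concerns the mutation with raised pressure. Cardiac muscle markers were lower, with a mean log2 difference of -0.59 and 18 of 18 members lower (adjusted p = 7.92e-09, and adjusted p = 0.788 with an estimated correlation). Tnni3 and Tnnt2, cardiac troponins, differed by -0.82 ± 0.31 and -0.78 ± 0.31, and Csrp3, a muscle LIM protein, by -0.85 ± 0.32. Tnnt2 had intensities of 2507 and 1218 in the high RVSP mice and 3229 and 2809 in the controls. R899X high RVSP 2 lay at -0.86 in the mean deviation of the list and R899X high RVSP 1 at -0.02. Without R899X high RVSP 2 the mean difference was -0.17 (adjusted p = 0.0555), and without R899X high RVSP 1 it was -1.02. Platelet and megakaryocyte markers were higher by 0.44, with 10 of 10 members higher (adjusted p = 3.87e-07, and adjusted p = 0.788 with an estimated correlation). Gp9, a subunit of the platelet von Willebrand factor receptor, differed by 0.74 ± 0.26, Itga2b, the platelet integrin subunit, by 0.49 ± 0.18, and Pf4, platelet factor 4, by 0.50 ± 0.19. Leaving out any 1 of the 6 arrays did not end this call with the preset correlation, but the mean was 0.28 without R899X high RVSP 2. Of the skeletal muscle markers, which did not pass as a list, 1 passed when adjusted over the list alone, Mb at -0.77 ± 0.20 (adjusted p = 0.0377), and 0 over all probe sets.

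Immediate early genes were higher by 0.38, with 18 of 20 members higher (adjusted p = 2.8e-05, and adjusted p = 0.788 with an estimated correlation). Atf3, a stress-induced transcription factor, was 0.80 ± 0.31 higher with intensities of 622 and 575 against 323 and 348 in the controls. Zfp36, which destabilises cytokine messages, differed by 0.61 ± 0.27, and Klf2 by -0.31 ± 0.15. Without control 1 or R899X high RVSP 1 the immediate early mean was 0.23 or 0.21 (adjusted p = 0.147 and 0.104), and with the beta-actin ratio as a covariate, chosen after seeing the data, it was -0.02. Cytokines and inflammatory mediators had a mean of 0.26, with 15 of 18 higher (adjusted p = 0.00244, and adjusted p = 0.788 with an estimated correlation). Csf2, GM-CSF, differed by 0.83 ± 0.33 and Osm, oncostatin M, by 0.68 ± 0.28; without R899X high RVSP 1 the mean was 0.20 (adjusted p = 0.0814). B cell and plasma cell markers were higher by 0.24, with 11 of 13 members higher (adjusted p = 0.0132, and adjusted p = 0.788 with an estimated correlation). Cd79a, part of the B cell receptor, differed by 0.70 ± 0.26. This list scored 0.38 in R899X high RVSP 1 and -0.04 in R899X high RVSP 2, and without R899X high RVSP 1 or control 2 its mean was 0.03 or 0.08 (adjusted p = 0.800 and 0.716). It was 0.40 without control 1 and 0.45 without R899X high RVSP 2. Ciliated cell markers had a mean of 0.31, with 14 of 14 higher (adjusted p = 0.000129, and adjusted p = 0.788 with an estimated correlation). Their mean was -0.02 without control 1, 0.64 without control 2 and 0.19 without R899X high RVSP 1 (adjusted p = 0.0814).

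Interferon-stimulated genes were lower than in controls by a mean of -0.45, with 18 of 21 members lower (adjusted p = 0.00026, and adjusted p = 0.788 with an estimated correlation). Igtp, an interferon-inducible GTPase, had intensities of 868 and 1063 in the high RVSP mice and 5964 and 1085 in the controls. Oas2, which makes oligoadenylates in response to double-stranded RNA, differed by -0.83 ± 0.28. Without control 1 the mean of the interferon list was -0.06 (adjusted p = 0.860), without R899X high RVSP 1 it was -0.35 (adjusted p = 0.0538), and without control 2 it was -0.84. BMP target genes had a mean of 0.13 with 11 of 14 higher, and did not pass (adjusted p = 0.0972).

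Among single genes, Tmem87a had the largest difference from control, 3.18 ± 0.71, with intensities of 725 and 713 in the high RVSP mice and 65.1 and 65.4 in the controls. In the normal RVSP mice the same probe set read 708 and 93.5. Its adjusted p was 0.801 in the limma fit of all 6 arrays. Tmem87a passed without R899X normal RVSP 1 or without R899X normal RVSP 2, with the difference unchanged at 3.18. The normal RVSP arrays enter this comparison only through the shared spread, so these fits add no evidence of a difference. With 1 of the other arrays left out Tmem87a did not pass. Norad, a long noncoding RNA, stood at 2.10 ± 0.58, Clic5, a chloride intracellular channel protein, at 1.84 ± 0.43, and Twsg1, an extracellular modulator of BMP signalling, at 1.53 ± 0.26. Ankrd63 had intensities of 175 and 148 against 435 and 721 in the controls, a difference of -1.71 ± 0.27. Sfrp5, a secreted Wnt antagonist, stood at -1.16 ± 0.29 and Ivd, an enzyme of leucine breakdown, at -0.94 ± 0.16. Other probe sets existed for 17 of the 24 named genes and at least 1 pointed the other way for 10, Clic5 and Norad among them. With limma, 0 probe sets passed (smallest adjusted p = 0.801); 1527 had an unadjusted limma p under 0.05 against 1351 expected by chance, and the ordinary linear model gave 0. The count was 1 with only the arrays of these groups. Fits that left 1 array in a group are not counted here, because that group then had no spread of its own.

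R899X high RVSP was next set against R899X normal RVSP, mice that share the transgene and differ in pressure. Cardiac muscle markers were lower by a mean of -0.72, with 18 of 18 members lower (adjusted p = 2.09e-13, and adjusted p = 0.885 with an estimated correlation). Ckm, muscle creatine kinase, had intensities of 292 and 162 against 550 and 437, a difference of -1.11 ± 0.29. Sln, sarcolipin of atrial muscle, differed by -0.96 ± 0.34. R899X normal RVSP 1 scored highest on this list at 0.49 and R899X high RVSP 2 lowest at -0.86. Interferon-stimulated genes were also lower, by -0.58, with 18 of 21 members lower (adjusted p = 9.83e-09, and adjusted p = 0.885 with an estimated correlation). Psmb8, a subunit of the immunoproteasome, had intensities of 1689 and 1750 against 2526 and 3058, a difference of -0.69 ± 0.22. Irf1 and Irf7, interferon regulatory factors, differed by -0.50 ± 0.17 and -0.52 ± 0.21. Control 2 scored -0.28 on this list, between R899X high RVSP 1 at -0.45 and R899X high RVSP 2 at -0.24. Leaving out any 1 array ended neither of these calls with the preset correlation. The cardiac mean was -0.30 without R899X high RVSP 2 and -1.14 without R899X high RVSP 1.

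**Figure D3:**
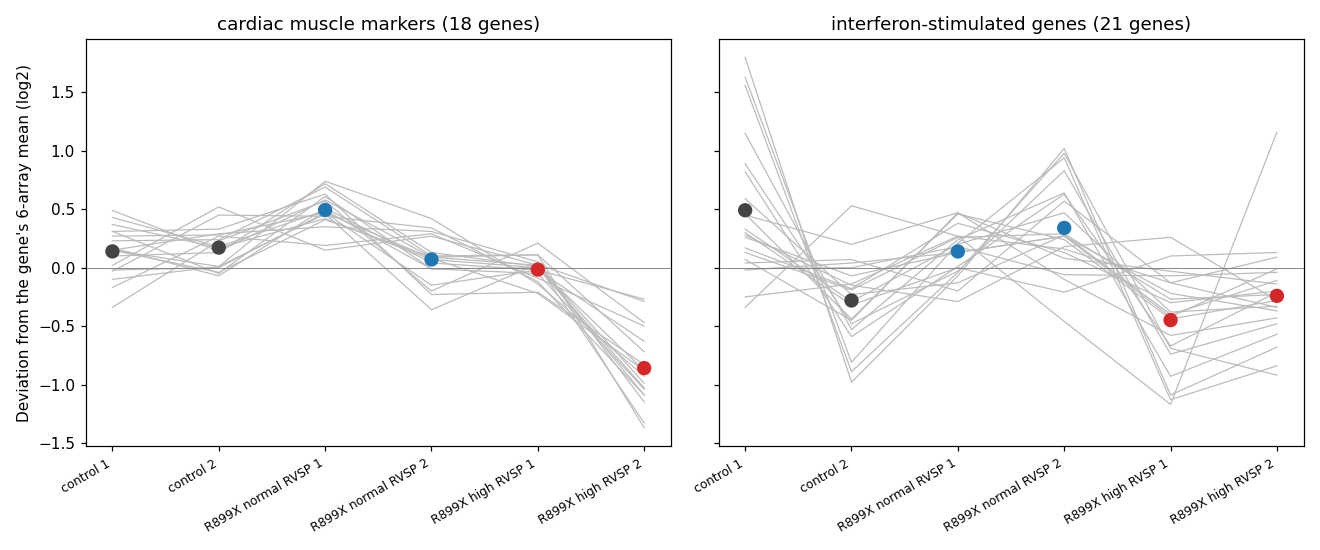
Deviation of each gene from its mean over the 6 arrays (log2) for 18 cardiac muscle markers (left) and 21 interferon-stimulated genes (right); each grey line is 1 gene and each coloured point the mean of the list on that array. The cardiac mean was -0.86 in R899X high RVSP 2 and -0.02 in R899X high RVSP 1; the interferon mean was 0.49 in control 1 and -0.28 in control 2.

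Smooth muscle contractile genes were lower in high than in normal RVSP by a mean of -0.25, with 16 of 17 members lower (adjusted p = 0.0012, and adjusted p = 0.885 with an estimated correlation). The members with the strongest statistics, Pln at -0.74 ± 0.32 and Ldb3 at -0.55 ± 0.30, encode phospholamban and a Z-disc protein that heart muscle also expresses. Without R899X high RVSP 2 the mean was -0.10 (adjusted p = 0.380), without R899X normal RVSP 1 it was -0.17 (adjusted p = 0.0675), and without R899X high RVSP 1 it was -0.40. Oxidative phosphorylation genes were lower by -0.15, with 21 of 23 lower (adjusted p = 0.00902, and adjusted p = 0.885 with an estimated correlation), with a mean of -0.09 without R899X normal RVSP 1 (adjusted p = 0.2499) and -0.14 without R899X high RVSP 2 (adjusted p = 0.123). Adipocyte markers were lower by -0.18 with 9 of 11 lower (adjusted p = 0.0470, and adjusted p = 0.885 with an estimated correlation), and 0.22 higher without R899X normal RVSP 2. The adipocyte mean was -0.58 without R899X normal RVSP 1 and -0.11 without R899X high RVSP 2 (adjusted p = 0.207). The call also ended without control 1, control 2 or R899X high RVSP 1 (adjusted p = 0.0545, 0.0564 and 0.0561). Heat shock and unfolded protein response genes were higher by 0.16, with 16 of 19 higher (adjusted p = 0.00264, and adjusted p = 0.885 with an estimated correlation); without R899X normal RVSP 1 the mean was 0.09 (adjusted p = 0.471). Ddit3, a transcription factor of endoplasmic reticulum stress, differed by 0.45 ± 0.16.

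Immediate early genes were higher by 0.28, with 16 of 20 higher (adjusted p = 0.000897, and adjusted p = 0.885 with an estimated correlation), and Myc stood at 0.57 ± 0.24. Without R899X normal RVSP 1 that mean was -0.08, and without R899X high RVSP 1 it was 0.10 (adjusted p = 0.433). It was 0.64 without R899X normal RVSP 2 and 0.45 without R899X high RVSP 2. Platelet and megakaryocyte markers were higher by 0.24, with 9 of 10 higher (adjusted p = 0.000897, and adjusted p = 0.885 with an estimated correlation). Gp1bb, a subunit of the same von Willebrand factor receptor as Gp9, stood at 0.47 ± 0.25. Without R899X high RVSP 2 the platelet mean was 0.08 (adjusted p = 0.380), without R899X normal RVSP 1 it was 0.16 (adjusted p = 0.212), and without R899X high RVSP 1 it was 0.40. B cell and plasma cell markers were higher by 0.25, with 11 of 13 higher (adjusted p = 0.00112, and adjusted p = 0.885 with an estimated correlation), and 0.04 or 0.09 higher without R899X high RVSP 1 or R899X normal RVSP 1 (adjusted p = 0.692 and 0.455). Their mean was 0.41 without R899X normal RVSP 2 and 0.46 without R899X high RVSP 2. Ms4a1, the B cell antigen CD20, stood at 0.59 ± 0.40. Skeletal muscle markers did not pass as a list, with 3 members higher, 4 lower and a median of -0.01. Still, 2 members, Mb and Ckm, passed when adjusted over the list alone (smallest adjusted p = 0.000533), and 0 over all probe sets. Ckm was given above among the cardiac muscle markers, and heart muscle also expresses Mb. These members therefore do not point to skeletal muscle apart from the cardiac result.

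Mb had intensities of 440 and 317 in high RVSP and 1158 and 1027 in normal RVSP, a difference of -1.51 ± 0.20. Apmap, an adipocyte membrane protein, stood at -2.44 ± 0.39, Zdhhc12 at -2.07 ± 0.29, and Cyp1a1, a target of the aryl hydrocarbon receptor, at -1.61 ± 0.38. The Apmap probe set was dim in high RVSP, with intensities of 67.2 and 19.9 against 293 and 267 in normal RVSP. Psmb9, another immunoproteasome subunit, had intensities of 1280 and 1569 against 2413 and 2872, a difference of -0.89 ± 0.19. In the other direction Mrps15 stood at 1.52 ± 0.40, Tia1, an RNA-binding protein of stress granules, at 1.21 ± 0.31, and Plcb1, a phospholipase C, at 1.10 ± 0.28. Of 12 genes with other probe sets, 6 had at least 1 that pointed the other way, among them Mrps15 with 2 of 2 and Tia1 with 3 of 4. With limma, 0 probe sets passed (smallest adjusted p = 0.9996); 707 had an unadjusted limma p under 0.05 against 1351 expected by chance, and the ordinary linear model gave 0. Counts from fits that left 1 array in a group are not given, because that group then had no spread of its own.

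Across both transgenic groups against control, ciliated cell markers were higher by 0.38 with 14 of 14 higher (adjusted p = 2.28e-06, and adjusted p = 0.723 with an estimated correlation), but by 0.05 without control 1 (adjusted p = 0.604) and by 0.71 without control 2. Platelet and megakaryocyte markers were higher by 0.32, with 10 of 10 members higher (adjusted p = 8.51e-05, and adjusted p = 0.723 with an estimated correlation); all 4 transgenic mice lay above both controls on this list, and without control 1 the adjusted p was 0.0513. Ppbp, a platelet chemokine, differed by 0.54 ± 0.28. Immediate early genes had a mean of 0.24 with 18 of 20 higher (adjusted p = 0.0116, and adjusted p = 0.892 with an estimated correlation), and Nr4a1, an orphan nuclear receptor, stood at 0.50 ± 0.27. The call ended without control 1 (adjusted p = 0.604), R899X normal RVSP 2 (adjusted p = 0.673) or R899X high RVSP 1 (adjusted p = 0.173), where the mean was 0.09, 0.06 and 0.16. It was 0.39 without control 2, 0.42 without R899X normal RVSP 1 and -0.06 with the beta-actin covariate. Cytokines and inflammatory mediators were higher by 0.18 with 13 of 18 higher (adjusted p = 0.0386, and adjusted p = 0.723 with an estimated correlation). Csf2 differed by 0.88 ± 0.28, with intensities of 139 to 168 in the 4 transgenic mice and 53.4 and 108 in the controls; the list's call ended without control 1, control 2, R899X normal RVSP 2 or R899X high RVSP 1 (adjusted p = 0.124, 0.146, 0.738 and 0.129). Its mean was 0.05 without R899X normal RVSP 2 and 0.31 without R899X normal RVSP 1. Cardiac muscle markers were lower by -0.23 with 15 of 18 lower (adjusted p = 0.0192, and adjusted p = 0.892 with an estimated correlation), and by -0.02 without R899X high RVSP 2 (adjusted p = 0.823). That call also ended without control 1, control 2 or R899X normal RVSP 2 (adjusted p = 0.0795, 0.260 and 0.323). The cardiac mean was -0.13 without R899X normal RVSP 2 and -0.44 without R899X high RVSP 1. Heat shock and unfolded protein response genes were lower by -0.14 with 14 of 19 lower (adjusted p = 0.0493, and adjusted p = 0.892 with an estimated correlation), and 0.05 higher without control 1 but -0.33 without control 2; the call also ended without R899X normal RVSP 1 or R899X high RVSP 1 (adjusted p = 0.231 and 0.108).

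**Figure D4:**
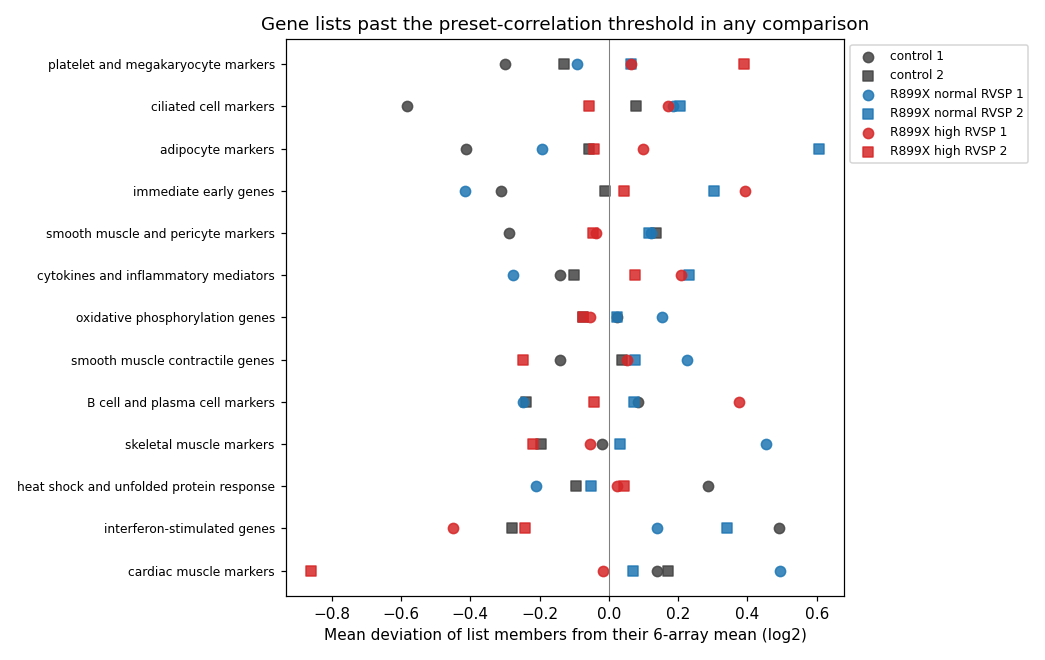
Mean deviation of the members of each gene list from their 6-array mean (log2, horizontal axis) for every list past the preset-correlation threshold in at least 1 comparison; each point is 1 array, with colour for the group and shape for the replicate. Control 1 lies at -0.58 for ciliated cell markers and R899X high RVSP 2 at -0.86 for cardiac muscle markers.

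Tmem87a stood at 2.49 ± 0.61 for all transgenic mice against control (adjusted p = 0.832), and at 3.17 (adjusted p = 0.00767) without R899X normal RVSP 2, the transgenic mouse that read near the controls, or 1.80 (adjusted p = 0.353) without R899X normal RVSP 1. Nrg1 stood at 1.48 ± 0.31 and Ntn5 at 1.45 ± 0.31, both against the dim control readings given above. Tspan18, a tetraspanin, stood at 1.36 ± 0.28 and Mid2 at 1.32 ± 0.23. Ate1, an arginyltransferase, had intensities of 332 to 537 in the 4 transgenic mice and 137 and 181 in the controls. Twsg1 differed by 1.25 ± 0.22. Ankrd63 stood at -1.25 ± 0.24, Itpkb, an inositol trisphosphate kinase, at -0.97 ± 0.27, and Nfib, a transcription factor of lung development, at -0.84 ± 0.23. Other probe sets existed for 18 of the 24 named genes, and at least 1 pointed the other way for 13 of them. Among these were Itpkb (1 of 1), Ate1 (2 of 4), Nfib (2 of 6), Twsg1 (1 of 2) and Tspan18 (1 of 2). With limma, 0 probe sets passed (smallest adjusted p = 0.832); 1601 had an unadjusted limma p under 0.05 against 1351 expected by chance, and the ordinary linear model gave 0. Values of the 4 transgenic mice and the controls did not overlap for 15.2% of probe sets, against 13.3% expected by chance. As in the other comparisons, counts from fits that left 1 array in a group are not given.

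The differences of the R899X normal RVSP and R899X high RVSP mice from the same 2 controls had a Pearson r of 0.599 across the 27022 probe sets, which are not independent replicates. Unchanged groups simulated against shared controls gave a mean r of 0.501 (0.466 to 0.533 over 200 simulations). The covariance was 0.0619, against a simulated 0.0495 (0.0456 to 0.0565). The sign was the same for 71.1% of probe sets, against a simulated 66.7%. At an unadjusted limma p under 0.05, 207 probe sets were higher in both, with 142 to 203 in the simulations and 16.8 for independent lists. Those lower in both numbered 163, with 136 to 208 in the simulations and 14.4 for independent lists. With 1 array left out, the r for unchanged groups itself depends on which group has 1 array. Without R899X normal RVSP 2 the r was 0.279, the lowest, against a simulated 0.408 (0.373 to 0.432), and without control 2 it was 0.798, the highest, against 0.667 (0.652 to 0.685). Without control 1 it was 0.650 and no longer above the simulated 0.667 (0.651 to 0.685). All these simulations gave the 3 groups equal spread. They also drew each probe set independently, so their ranges leave out the correlation between probe sets and are too narrow for real arrays. With the spread of each group taken from its own 2 arrays, a simulation chosen after seeing the result, unchanged groups gave an r of 0.573 (0.551 to 0.591), a covariance of 0.0585 (0.0552 to 0.0633) and the same sign for 69.4% of probe sets (68.5 to 70.2). The observed covariance lay inside that range, and the observed r and share of equal signs lay above theirs. Probe sets were drawn independently here too, so a value outside these ranges does not show a change shared by the transgenic groups.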

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

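The tests of the array distances, of the high RVSP 1 array, of immune cell lists, of random gene sets and of pressure for the interferon genes were chosen after the result was seen; those on second probe sets of interferon genes, on cardiac genes outside the lists and on other pairings of arrays were written before theirs.

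Within the 4 transgenic arrays, 4 of 45 lists and 1 of 7 probe sets of the fixed genes had 1 array far from the other 3; chance alone sets apart about 1 in 20 groups. MHC class II antigen presentation genes scored 0.30 in R899X normal RVSP 2, against -0.13 to -0.06 in the others. Potassium and calcium channels scored -0.0695 in R899X high RVSP 2, against 0.02 in the others. Ciliated cell markers scored -0.0571 in R899X high RVSP 2, against 0.17 to 0.20. Mast cell and basophil markers scored -0.25 in R899X normal RVSP 1, against 0.04 to 0.06. The intermediate Bmpr2 probe set read 657 in R899X normal RVSP 1, against 1928 to 2170. It also read 436 in control 1 against 2047 in control 2, so it was over 2-fold lower in replicate 1 of both groups. The other Bmpr2 probe sets were not: the brightest read 19768 and 15872 in the controls and 18835 and 16849 in the R899X normal RVSP mice. Outside the main measurement, the control probe set for the 3' end of Tfrc, the transferrin receptor, had a mean 1.94 times that of the controls, with 181, 272, 265 and 409 in the transgenic mice and 130 and 160 in the controls. It was picked from the mouse control probe sets because all 4 transgenic mice lay above both controls. That separation is therefore no evidence by itself.

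Control 1 and R899X normal RVSP 1 lay farther from the other arrays. In both groups 20 probe sets were over 2-fold higher in replicate 1 than in replicate 2. The differences within the 2 groups had a Pearson r of 0.15 over all probe sets. Over 2-fold lower in replicate 1 of both groups were 174 probe sets, against 29.8 if the differences were independent. The other 286 probe sets of the same genes had a median difference of -0.0770 ± 0.0326 (bootstrap SE) against -1.47 for the chosen ones. Any probe set of these genes that was itself over 2-fold lower in both groups counted among the chosen ones. This exclusion and the choice of extreme probe sets both widen the contrast. The remaining probe sets mostly did not share the difference, but how far transcript amounts account for it was not settled. Shorter labelled RNA may contribute: the beta-actin ratio was at least 1.64 in these arrays and at most 1.45 in the others, but the Gapdh ratio did not single them out, so this stays open. The 18S ribosomal RNA control probe set read 279 in control 1 and 73.3 in R899X normal RVSP 1, against 392 to 1229 in the others. The 3' probe set of the added control transcript CreX read 28535 and 21978, against 17833 to 22028. The labels name nothing that these 2 mice share, so no biological explanation beyond the transcript amounts was tested.

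Cardiac muscle markers were lower in R899X high RVSP 2 than in R899X high RVSP 1 for 18 of 18 genes. Of 47 further cardiac genes in no list, 41 were lower, with a median of -0.36 ± 0.07 (bootstrap SE), between the bounds of -0.2 and -0.4 set beforehand, so less cardiac muscle in this tissue sample may account for the pattern but was not established. Raised pressure also stays open: R899X high RVSP 1 lay 0.23 below the mean of the 4 arrays of the other groups, a value of -1.25 in units of their SD. With 1 array low, an effect of the group and the tissue taken from 1 mouse cannot be told apart.

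Interferon-stimulated genes differed between mice of 1 group, by 0.77 ± 0.21 (SE over 21 genes) between control 1 and control 2. The labels do not state the RVSP of the controls, so pressure was not tested for this difference. Independent noise of single probe sets is argued against as the whole cause, because the largest mean difference in 10000 random sets of 21 genes of like intensity was 0.37. More immune cells could contribute: the immune cell list that differed most, B cell and plasma cell markers, differed by 0.32 ± 0.08, and the mast cell list was too variable to exclude. The 7 second probe sets had a median difference of 1.03 ± 0.63 (bootstrap SE), in the same direction but too variable to decide alone. For the mean of -0.58 in R899X high against normal RVSP, pressure stays open: control 1 lay 0.73 ± 0.21 above the higher of the high RVSP arrays, while control 2 differed from it by -0.0394 ± 0.0631 (SE over 21 genes).

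Over the 15 ways to pair the 6 arrays, the real groups gave 1011 probe sets with an unadjusted limma F-test p under 0.05, and 8 pairings including the real one gave at least as many. The highest other pairing gave 2958, and the 3 highest all put control 1 with R899X normal RVSP 1, which points to a structure of the samples. With 15 pairings no share under 0.05 is possible.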

How the results depend on the processing

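The alternatives without control 1 and R899X normal RVSP 1 together and with the beta-actin 3'/5' ratio as a covariate, the tests made with them, and the simulations of r with arrays left out or with each group's own spread, were chosen after the result was seen. No paired analysis was possible because the labels pair no mice across groups. The beta-actin ratio was 1.89 and 1.45 in the controls, 1.64 and 1.31 in the R899X normal RVSP mice and 1.36 and 1.27 in the R899X high RVSP mice. It thus partly follows the groups. A call lost or reversed with this covariate does not tell RNA quality from an effect of the group. A group left with 1 array was assumed to vary like the others. Without control 1 and R899X normal RVSP 1 together, that spread came from R899X high RVSP alone. The mean variance between its 2 arrays was 0.0582, against 0.117 in control and 0.121 in R899X normal RVSP. The cause of the shifts below was not tested.

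No named gene passed in the fit of all 6 arrays, and across the alternatives 1710 results of named genes stayed on the same side with the same direction. Staying on the same side means that they again did not pass. Named genes were chosen for arrays that do not overlap between the sides, so leaving out arrays could not reverse their direction. That count is therefore no check of these genes. Tmem87a passed in R899X high RVSP against control with only the arrays compared (adjusted p = 0.0204) and without R899X normal RVSP 1 or 2 (adjusted p = 0.0302 and 0.0123), and in all R899X against control without R899X normal RVSP 2 (adjusted p = 0.00767). With control 1 and R899X normal RVSP 1 left out together, 29 named results passed, and the numbers of probe sets past the threshold were 131 for R899X normal RVSP against control, 313 for R899X high RVSP against control, 56 for R899X high against normal RVSP and 228 for all R899X against control, each 0 in the fit of all 6 arrays. With only the arrays compared, 1 probe set passed in R899X high RVSP against control. That alternative has no separate form for all R899X against control. Leaving out 1 array gave 0 to 4, 0 to 2, 0 to 43 and 0 to 6 probe sets in the same order. No probe set passed in the other settings.

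Of the 28 list calls, 28 were lost with an estimated correlation and with fry in either form, which gave 0 lists in each comparison. With array weights 28 calls stayed, but this could not test outlying arrays. The arrays of a group differ equally from its mean, so weights cannot favour either, and the group differences were unchanged. With camera on ranks 25 calls stayed, with quantile normalization 24, with the mean of a gene's probe sets 22 and without the filter on dim probe sets 21. With the beta-actin covariate 11 stayed, 15 were lost and 2 reversed, and without control 1 and R899X normal RVSP 1 together 13 stayed, 10 were lost and 5 reversed. Leaving out 1 array kept 13 to 22. Without the filter on dim probe sets, 3 lists passed in R899X normal RVSP against control in place of 6. With the beta-actin covariate, 4 passed in R899X high RVSP against control in place of 7, and 2 in all R899X against control in place of 6. The latter count was 10 without control 1 and R899X normal RVSP 1 together and 3 with the mean of a gene's probe sets. Leaving out 1 array gave 3 to 11, 4 to 14 and 3 to 14 lists in R899X normal RVSP, high RVSP and all R899X against control, and 3 calls were ended by no single array.

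Directions reversed for 8 calls. Without control 1 and R899X normal RVSP 1 together, the mean was 0.0427 for heat shock genes and -0.0209 for smooth muscle and pericyte markers in R899X normal RVSP against control, -0.0208 for ciliated markers in R899X high RVSP against control, -0.0832 for immediate early genes in R899X high against normal RVSP, and 0.0852 for heat shock genes in all R899X against control. With the beta-actin covariate, immediate early genes had a mean of -0.0165 in R899X high RVSP against control and -0.0584 in all R899X against control. With 1 array left out, the ranges were -0.0186 to 0.407 for smooth muscle and pericyte markers, -0.0208 to 0.639 for ciliated markers, -0.0832 to 0.635 for immediate early genes in R899X high against normal RVSP, -0.579 to 0.220 for adipocyte markers in R899X high against normal RVSP, and -0.335 to 0.0458 for heat shock genes in all R899X against control.

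The r between the differences of the transgenic groups from control was 0.710 without control 1 and R899X normal RVSP 1 together, where unchanged groups gave 0.578, and 0.279 to 0.798 with 1 array left out. It was above the simulated range for 4 of these 6 arrays, and below it without control 1 (0.650 against 0.667) and without R899X normal RVSP 2 (0.279 against 0.408). These ranges come from independent probe sets, so lying outside them decides nothing about shared changes. With each group's own spread, unchanged groups gave 0.573 in place of 0.501, against 0.599 observed. The first principal component held 29.7% of the variance without the filter on dim probe sets, against 35.9% with it. Signal near background limits the dim probe sets, and 18015 were not tested for that reason.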

Other observations

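The liver genes below were chosen after the values were seen, and no explanation is offered for any value in this part. Control 2 had the highest intensity of the 6 arrays for 9 of 9 measured genes of a list of 25 that are abundant in liver, written after Alb and Ttr had been seen among the most variable genes. Serpina1c, Apoa2 and Fabp1 stood among those most variable genes too, so the count of 9 is not an independent check. Alb, albumin, read 2464 in control 2 and 54.6 to 390 elsewhere. Ttr, transthyretin, read 996 in control 2 and at most 246 elsewhere, and Serpina1c, an antitrypsin, 1205 and at most 221. The mean deviation of the 9 genes was 1.78 in control 2, against -0.74 in control 1. It was -0.58 and -0.03 in the R899X normal RVSP mice and -0.85 and 0.41 in the R899X high RVSP mice.

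Red cell and reticulocyte markers differed widely within each group, at -0.39 and 0.39 in the controls, 0.28 and -0.55 in the R899X normal RVSP mice and -0.69 and 0.95 in the R899X high RVSP mice. Adipocyte markers scored 0.61 in R899X normal RVSP 2 and -0.19 in R899X normal RVSP 1. Skeletal muscle markers scored 0.45 in R899X normal RVSP 1 and 0.03 in R899X normal RVSP 2. Alveolar type 1 and type 2 markers stayed between -0.13 and 0.08 on all 6 arrays. TGF-beta target genes lay between -0.06 and 0.08, and receptors and Smads of both pathways between -0.03 and 0.02.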
